A study of Mus musculus with 12 samples.

How the data were processed

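RNA was measured by sequencing in 12 mouse colon libraries, 4 of normal colon (N), 4 of tumours of the genotype BrafV600E;Tgfbr2-/- (BT-T) and 4 of tumours that also lack Rnf43, Znrf3 and p16 Ink4a (BTPRZ-T). Per the labels' protocols, libraries were made with a stranded poly(A) kit and sequenced as single reads of 100 bases. Per the submitters' processing notes, reads were converted with bcl2fastq 2.20, aligned to the mm10 genome with STAR 2.4.2a and analysed with edgeR 3.16.5 and limma; HTSeq is also listed, without its step. The deposited files give raw read counts per gene for each library, with no normalization by the authors. Their layout is the gene count output of STAR, with 1 unstranded and 2 stranded columns of counts for 24054 gene symbols. The files count 0 reads at several loci, so near-identical paralogs are represented by their uniquely placed reads alone. The annotation behind the symbols is not given in the sources used here.

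The stranded column with more gene reads in every library (column 4) was used, and the other strand held 0.813 to 0.984% as many reads. Gene reads came to 15.7M to 26.1M per library. Genes with too few reads were removed with filterByExpr of edgeR, by group, which left 14860 genes. Libraries were scaled by TMM factors, and levels are CPM on that scale, reads of a gene per library scaled to a common total. A negative binomial quasi-likelihood model (edgeR 4.0.16 under R 4.3.3; glmQLFit with robust estimation, glmQLFTest) was fitted to all 12 libraries with 1 mean per group and no other term. The 3 comparisons were BT-T against N, BTPRZ-T against N and BTPRZ-T against BT-T, each two-sided. The last is also the test of the difference between the other 2 effects. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The common biological coefficient of variation was 0.501. Each ± after a mean CPM is the SD over 4 libraries, and each ± after a log2 fold change is its standard error. Where every library of a group held no read of a gene, the fold is a lower bound set at 3 reads over the group. Where a group held 1 to 3 reads in all, the ratio is given with its 95% counting interval. Reads are not independent molecules here, so intervals and floors cover counting error only.

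Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. There were 37 lists of pathways, cell types and tissue programmes, with 667 distinct genes, of which 35 stand in 2 or more lists. The 35 lists with at least 5 tested members were tested and adjusted together by Benjamini-Hochberg. For each list, the genes called over all genes are counted, and the count with p adjusted over the list alone is given beside it. The lists hold textbook markers that were not chosen on these libraries. Cell type markers may not be exclusive to their cell type. In N replicates 1, 3 and 4, 16 of 18 macrophage markers stood at 1 CPM or more on average. Counts of whole tissue cannot tell which cells gave them. For 3 list symbols, the older symbol used in the files was taken.

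The groups, comparisons, tests, lists, named genes and most alternatives were fixed before the data were examined. Named genes were chosen by rule in each comparison. The first part takes the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups, leaving out predicted genes and sex-linked transcripts. The second takes up to 4 members with the lowest adjusted p of each list described. The third takes the targeted genes Braf, Tgfbr2, Rnf43, Znrf3 and Cdkn2a. The fourth takes a fixed set of markers such as Axin2, Lgr5, Muc2 and Col1a1. Some genes that these rules take are not reported here. Positions are from GENCODE M21 on GRCm38, matched by symbol; genes carried under an older symbol in the files have none here.

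The alternatives were RLE and upper quartile factors, no filter, a filter of 2 CPM in 4 libraries, DESeq2 1.42.0, limma with voom, the unstranded column, the 2 compared groups alone, a term for the replicate number, no robust estimation, a test against a fold of 1.5, the estimated correlation in camera, and leaving out each library in turn. The labels do not say that the replicate numbers pair the samples, so the replicate term is an alternative alone. Transcript length is that of the longest transcript of a gene in GENCODE M21. After the data were examined, 4 kinds were added: a fit with the trend on transcript length removed (14208 genes have a length), voom with sample quality weights, a fit without the 3 libraries with the fewest detected genes (N replicate 2, BTPRZ-T replicates 1 and 4), and fits without single libraries of the group outside a comparison.

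The pipeline was tested on counts simulated from a negative binomial with each gene's mean and dispersion. In these, 67, 67 and 66 genes were given a change of 1.5, 2 and 4-fold in 1 group. In the 3 comparisons edgeR called 28, 29 and 26 of 66 genes with a 4-fold change and at most 3 of 67 with a 2-fold change, with 3, 1 and 0 false calls among 32, 33 and 26. DESeq2 made 34, 47 and 25 false calls among 86, 105 and 84. A list shifted by 1 log2 unit was found by camera in each comparison. Other splits of the 8 libraries of a comparison into groups of 4 (35 splits) were fitted in the same way. The overlap of the 2 tumour effects was compared with 20 simulations in which tumour libraries do not differ from N, and with fits in which the N libraries were divided between the comparisons. No library was left out of the reported values.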

Results

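Poly(A) RNA was sequenced from 12 mouse colon samples in 3 groups of 4 libraries. The N group is normal colon of the wild type. The BT-T group is tumour that grew from engrafted colonic organoids with the activated kinase allele BrafV600E and without Tgfbr2, a receptor for the growth factor TGF-beta. The BTPRZ-T group is tumour from organoids that also lacked Rnf43 and Znrf3, ubiquitin ligases that remove WNT receptors from the cell surface, and p16 Ink4a, a cell cycle inhibitor encoded by Cdkn2a. The labels give the immunodeficient strain NSG for every library and do not say whether the 4 libraries of a group came from separate animals. Reads in genes came to 17669408, 19191146, 18187888 and 16478975 in N replicates 1 to 4, to 26052772, 18811457, 21885703 and 18990528 in BT-T, and to 15732004, 19524776, 18096551 and 21160052 in BTPRZ-T. Of 24054 genes in the files, 14860 had enough reads to be tested. Levels are CPM after TMM scaling, as mean ± SD over 4 libraries, and log2 fold changes are given ± SE.

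Libraries of 1 group differed in composition. In N replicate 2, transcripts of ribosomal protein genes took 10.96% of gene reads, against 1.59 to 1.94% in the other N libraries. This library held reads of 14175 genes, against 16152 to 16432 in the other N libraries. Its levels fell with transcript length (slope -0.91 log2 units per doubling, against 0.19 to 0.28 in the other N libraries). Ribosomal protein transcripts took 2.26 ± 0.361% of gene reads in BT-T and 5.73 ± 2.37% in BTPRZ-T, with 9.09% in BTPRZ-T replicate 1. BTPRZ-T replicate 4 had the fewest genes with a read, 13450, and BT-T replicate 1 the most, 17266. The slope on transcript length was 0.064 to 0.304 in BT-T and -0.507 to 0.110 in BTPRZ-T. The first principal component held 32.8% of the variance and the second 29.6%. On the first, N replicate 2 lay at 123 and BTPRZ-T at 21.1 to 101. The other N libraries and BT-T lay at -80.9 to -23.1, so this component did not separate tumours from N. Across genes, log CPM of replicates correlated with r between 0.788 and 0.982, and genes are not independent replicates. The Y-linked transcript Ddx3y stood at 33.4 to 43.7 CPM in N replicates 1, 2 and 3. In N replicate 4, with 1153 CPM of Xist, the RNA that silences an X chromosome in female cells, Ddx3y stood at 0.0675 CPM. Both were present in BT-T replicates 2, 3 and 4 and in BTPRZ-T replicate 2. Xist stood at 95.8 to 730.4 CPM there, and Ddx3y at 12.7 to 47.6 CPM. The other tumour libraries held Xist and at most 2 reads of Ddx3y. Y-linked transcripts were thus all but absent from BTPRZ-T replicates 1, 3 and 4, N replicate 4 and BT-T replicate 1. Sex was not balanced over the groups, so it is partly confounded with genotype in the comparisons with BTPRZ-T.

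**Figure D1:**
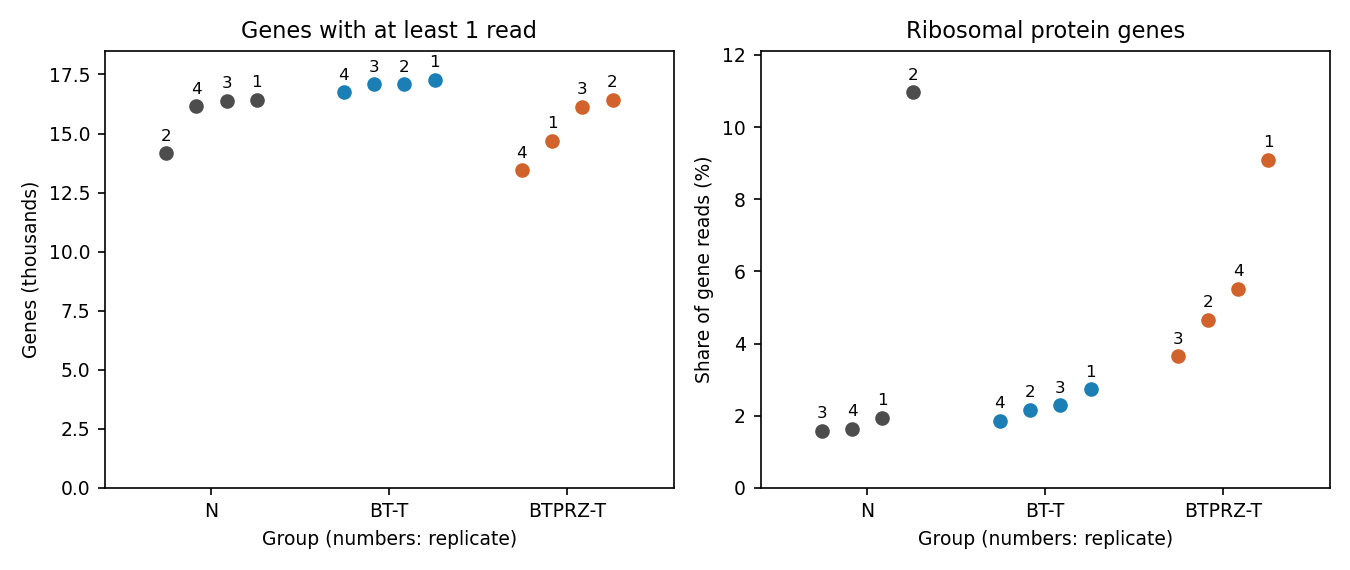
Composition of the 12 libraries, 1 point per library. The left panel shows genes with at least 1 read and the right panel the share of gene reads from ribosomal protein genes in percent, by group. N replicate 2 lies at 14175 genes and 10.96%, apart from the other N libraries.

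Transcripts of the edited genes were counted over whole genes, so these counts cannot show whether an edit is present. Cdkn2a (chromosome 4, 89274471 to 89294653 on GRCm38) was the clearest of them. It stood at 0.230 to 0.354 CPM in the N libraries, 8.21 to 15.8 CPM in BT-T and 18.8 to 31.4 CPM in BTPRZ-T, where p16 Ink4a is deleted; the Arf transcript shares exons with p16 Ink4a. The log2 fold change against N was 5.24 ± 0.37 in BT-T (edgeR adjusted p = 2.86e-05) and 6.38 ± 0.38 in BTPRZ-T (adjusted p = 8.48e-06). Between the tumour groups it was not called (adjusted p = 0.0905, and 0.0158 without N replicate 2, higher in BTPRZ-T). Rnf43 rose in BTPRZ-T, from 43.1 ± 23.1 to 146 ± 47.7 CPM (log2 fold change 1.76 ± 0.38, adjusted p = 0.0112), and was not called in BT-T (adjusted p = 0.329). With N and BTPRZ-T alone in the fit, the adjusted p of Rnf43 was 0.0541. Tgfbr2 stood at 194 ± 90.2 CPM in N, 417 ± 87.7 in BT-T and 199.6 ± 51.2 in BTPRZ-T. Its adjusted p for BT-T against N was 0.0874 with all libraries and 0.0418 without N replicate 2. Braf stood at 53.5 ± 27.5, 53.4 ± 6.11 and 31.5 ± 18.5 CPM, and Znrf3 at 23.9 ± 15.8, 25.6 ± 4.58 and 28.4 ± 8.58 CPM. Neither was called with all libraries, and without N replicate 2 the adjusted p of Braf for BTPRZ-T against N was 0.0369.

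The first comparison asked which transcripts separate tumours with the Braf and Tgfbr2 edits from normal colon. Transcripts of mature absorptive cells were much scarcer in BT-T than in N, and transcripts of fetal-like epithelium and matrix-degrading enzymes were more abundant. Slc9a3, the apical sodium-proton exchanger of absorptive cells (chromosome 13, 74121457 to 74169442), fell from 233 ± 193 CPM in N to 1.15 ± 0.685 in BT-T (log2 fold change -7.63 ± 0.91, n = 4 each, edgeR adjusted p = 0.000562). Fabp2, a fatty acid-binding protein of enterocytes, fell by 7.32 ± 0.78 on the log2 scale, from 350.1 to 2.17 CPM. Col10a1, a collagen chain of hypertrophic cartilage (chromosome 10, 34389981 to 34397085), rose from 0.866 ± 1.24 to 249 ± 139 CPM (log2 fold change 8.18 ± 1.32, adjusted p = 0.00282). In all, edgeR called 1274 of 14860 genes, 843 higher and 431 lower in BT-T. Of these, 797 were at least 2-fold higher and 362 at least 2-fold lower. The count was 757 without N replicate 1, 2030 without N replicate 2 (1172 higher), and 624, 688 and 722 without BT-T replicates 2, 3 and 4. DESeq2 called 2394 genes and a test against a fold of 1.5 called 684, while 4359 were called without the 3 libraries with the fewest detected genes and 6156 by voom with sample quality weights.

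Absorptive and goblet cell lists were lower in BT-T, and the enteroendocrine list at the preset correlation alone. Of 28 tested absorptive colonocyte markers, 12 fell; adjusted over the list alone, 18 fell and 1 rose. The list stood below other genes (camera adjusted p = 1.51e-11). Cyp2c55 fell by 4.20 ± 0.57 on the log2 scale. Among the other genes with the largest falls were the sulphate transporter Slc13a1 (-8.14 ± 1.05), the bile acid transporter subunit Slc51a (-7.51 ± 1.55), the amino acid transporter subunit Slc3a1 (-5.94 ± 1.16) and Tmigd1 (-5.28 ± 1.02). The glucuronosyltransferase gene Ugt2b5 had 3 reads in BT-T and 1270 in N, a ratio of N to BT-T with a 95% counting interval of 210.4 to 2992, and Ugt2b36 fell by 5.73 ± 1.15. Cyp4f14 (-5.93 ± 1.25) lost its call without BT-T replicate 2 (adjusted p = 0.0505). Krt20, a keratin of differentiated colonocytes, had an adjusted p of 0.0470. It lost the call when any of N replicates 1, 3 and 4, the 4 BT-T libraries or BTPRZ-T replicates 1 and 2 was left out (adjusted p 0.0506 to 0.144). Car1 stood at 1826 ± 963 CPM in N and 606 ± 432 in BT-T (adjusted p = 0.0634, and 0.0459 and 0.0171 without N replicate 2 and BT-T replicate 4). Of 20 goblet cell markers, 6 fell (8 adjusted over the list alone; camera adjusted p = 1.64e-05). They included the mucin Muc2 (-3.46 ± 0.69) and the secretory lineage factors Spdef (-2.09 ± 0.37) and Atoh1 (-1.46 ± 0.30). Of 19 enteroendocrine markers, 1 fell, the proglucagon gene Gcg (-2.67 ± 0.44), and the count was the same adjusted over the list alone. The list stood lower (camera adjusted p = 0.00742; adjusted p = 0.162 with an estimated correlation). Of 16 colon identity transcription factors, 3 fell and 2 rose (4 and 2 adjusted over the list alone). The intestinal factors Cdx2 (-1.67 ± 0.30) and Cdx1 (-1.13 ± 0.23) fell and Hoxd12 rose (6.12 ± 0.82), and the list as a whole was not called (camera adjusted p = 0.137, and 0.00421 without N replicate 2).

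Fetal-like and squamous lists were higher in BT-T, and the gastric list at the preset correlation alone. Of 23 fetal-like and YAP-linked regeneration genes, 10 rose (15 adjusted over the list alone; camera adjusted p = 5.03e-15). The surface glycoprotein Msln rose by 5.64 ± 0.64 on the log2 scale and Ly6a, a marker of regenerating epithelium, by 2.31 ± 0.51. Of 16 gastric and serrated lesion markers, 5 rose and 2 fell (5 and 3 adjusted over the list alone). Msln and the water channel Aqp5 (4.94 ± 0.93) were among those that rose. The list stood higher (camera adjusted p = 0.00604; adjusted p = 0.130 with an estimated correlation). The gastric marker Anxa10 had no read in N or BT-T, and Muc5ac had 2 reads in N and 3 in BT-T. Of 11 squamous and basal keratin genes, 1 rose, Krt4 (6.67 ± 0.70); adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 0.00128). Other genes among the largest rises were the serine protease Prss22 (6.98 ± 0.62), Dynap (7.59 ± 1.14), Megf11 (6.75 ± 0.82) and the metalloprotease Adam28, with 937 reads in BT-T and 3 in N (95% counting interval of the ratio 73.2 to 1042). Stem cell markers moved in both directions. Of 16, 2 rose and 1 fell, also when adjusted over the list alone, among them Clu (3.54 ± 0.61) and Aqp4 (-3.42 ± 0.48). The list's median was -0.00 and its mean 0.18 (camera adjusted p = 0.933). Lgr5, a marker of crypt stem cells, stood at 20.1 ± 4.11 CPM in N and 24.7 ± 4.13 in BT-T (adjusted p = 0.603).

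TGF-beta and p53 lists were higher in BT-T, and MAPK and WNT lists at the preset correlation alone. Of 19 TGF-beta response genes, 8 rose (11 adjusted over the list alone; camera adjusted p = 6.29e-10). Their median log2 fold change was 1.03, beside 2.73 for fibroblast, 2.29 for macrophage and 1.13 for endothelial markers. The genes that rose included the ligand Tgfb1 (2.86 ± 0.40), Pmepa1 (2.45 ± 0.34) and Tgif1 (1.03 ± 0.18). Smad7 was not called (-0.15 ± 0.36, adjusted p = 0.857). Of 26 MAPK output genes, 7 rose and 1 fell (14 and 1 adjusted over the list alone). The urokinase receptor Plaur (2.10 ± 0.25), the EGF receptor ligand Hbegf (1.53 ± 0.23) and Ier3 (2.63 ± 0.41) rose. The MAPK list stood higher (camera adjusted p = 9.78e-09; adjusted p = 0.0916 with an estimated correlation). The phosphatase Dusp6 stood at 80.1 ± 17.4 and 109.7 ± 19.6 CPM (adjusted p = 0.289). Of 23 WNT pathway targets, 3 rose (6 adjusted over the list alone). They included the secreted WNT antagonists Dkk2 (2.71 ± 0.55) and Wif1 (1.70 ± 0.41). Wif1 lost its call without N replicates 1 or 3 or BT-T replicates 2, 3 or 4 (adjusted p 0.0527 to 0.0855). The WNT list was called higher (camera adjusted p = 0.0240; adjusted p = 0.480 with an estimated correlation) and was not called without N replicate 2 (adjusted p = 0.299) or BT-T replicate 3 (adjusted p = 0.0529). Axin2, a feedback target of WNT signalling, stood at 64.0 ± 29.8 and 38.7 ± 3.48 CPM (adjusted p = 0.244, and 0.00685 without N replicate 2, lower in BT-T). Of 20 p53 and senescence genes, 6 rose, the same number adjusted over the list alone (camera adjusted p = 2.24e-05), among them Cdkn2a and Igfbp3 (2.24 ± 0.30).

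Matrix and epithelial-mesenchymal lists were higher in BT-T, and fibroblast, endothelial and immune lists at the preset correlation alone. Of 20 fibroblast markers, 14 rose (17 adjusted over the list alone). Col1a1 rose from 242 ± 95.5 to 3180.3 ± 991 CPM, Col5a2 by 3.24 ± 0.38 and the proteoglycan Dcn by 2.42 ± 0.34 on the log2 scale. The fibroblast list stood higher (camera adjusted p = 2.08e-19; adjusted p = 0.0558 with an estimated correlation). Of 20 matrix remodelling enzymes, 14 rose (16 adjusted over the list alone; camera adjusted p = 3.72e-20), such as the plasminogen activator Plat (3.55 ± 0.34), Adamts4 (3.32 ± 0.35) and the collagenase Mmp13 (4.52 ± 0.73). Of 20 epithelial-mesenchymal transition genes, 12 rose (14 adjusted over the list alone; camera adjusted p = 2.82e-13), with Cdh11 (2.59 ± 0.40) and Loxl2 (1.72 ± 0.29) among them. Acan (7.33 ± 0.85) and Epyc, proteoglycan genes of cartilage, and the integrin-like gene Itgbl1 were among the largest rises. Epyc had 460 reads in BT-T and Itgbl1 739, each against 1 read in N (95% counting intervals of the ratio 56.4 to 12509 and 90.8 to 20079.5). Epyc lost its call without N replicates 1, 3 or 4 or BT-T replicates 2 or 4 (adjusted p 0.0565 to 0.0879). Itgbl1 lost it without any N library, BT-T replicates 2, 3 or 4, or BTPRZ-T replicate 2 (adjusted p 0.0543 to 0.0998). Of 18 endothelial markers, 6 rose (10 adjusted over the list alone), with Cdh5, the cadherin of endothelial junctions, higher by 3.02 ± 0.38 (camera adjusted p = 4.03e-08; adjusted p = 0.0916 with an estimated correlation). Of 18 macrophage markers, 8 rose (13 adjusted over the list alone), such as Emr1 (2.86 ± 0.53) and the growth factor receptor Csf1r (2.97 ± 0.61; camera adjusted p = 6.29e-10; adjusted p = 0.110 with an estimated correlation). Of 14 neutrophil markers, 5 rose and 1 fell (7 and 1 adjusted over the list alone). Csf3r rose by 3.87 ± 0.60 and Cd177 fell by 1.99 ± 0.33 (camera adjusted p = 1.89e-05, and 0.0916 with an estimated correlation). In the N libraries Cd177 stood at 65.8 to 133 CPM and Csf3r at 0.709 to 2.37, so Cd177 may come from cells other than neutrophils. Of 21 cytokine and chemokine genes, 9 rose; adjusted over the list alone, 15 rose and 1 fell. The chemokine Cxcl5 (6.64 ± 1.01), Il1a (5.54 ± 0.88) and Ccl3 (4.91 ± 0.93) rose (camera adjusted p = 5.21e-10; adjusted p = 0.106 with an estimated correlation). Beside the macrophage values stands the list's mean log2 CPM in single N libraries, 4.15 in N replicate 2 and 2.22 to 3.49 in the others.

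Interferon and fatty acid oxidation lists were lower in BT-T. Of 26 interferon response genes, 11 fell (22 adjusted over the list alone; camera adjusted p = 5.23e-13), with Isg15 at -3.53 ± 0.47 and Ifit2 at -2.25 ± 0.33. Of 23 genes of fatty acid oxidation and ketogenesis, 9 fell (16 adjusted over the list alone; camera adjusted p = 3.03e-09), with the ketone body enzyme Bdh1 at -1.27 ± 0.20. Of 28 oxidative phosphorylation genes, 5 fell (27 adjusted over the list alone), among them the complex I subunit Ndufs1 (-0.83 ± 0.17; adjusted p = 0.0568 without BT-T replicate 2). The list was called (camera adjusted p = 9.39e-11; adjusted p = 0.249 with an estimated correlation). Its mean log2 CPM was 9.20 in N replicate 2 and 7.33 to 7.42 in the other N libraries, and its median log2 fold change was -1.52 with that library and -0.63 without it. Of 20 smooth muscle markers, 1 fell, Ldb3 (-1.27 ± 0.29), also when adjusted over the list alone. It lost its call without BT-T replicates 2 or 3 (adjusted p 0.0743 to 0.0789). The smooth muscle list stood lower (camera adjusted p = 2.87e-05; adjusted p = 0.299 with an estimated correlation). Of 9 adipocyte markers, 2 fell (5 adjusted over the list alone; camera adjusted p = 0.00396), among them the secreted protease Cfd (-6.22 ± 1.26; adjusted p = 0.0660 without BT-T replicate 2). The proliferation list was called lower (camera adjusted p = 0.0229; adjusted p = 0.578 with an estimated correlation). It was not called without N replicate 2 (adjusted p = 0.183), N replicate 3 (adjusted p = 0.183) or BT-T replicate 4 (adjusted p = 0.0608). Mki67, a marker of cycling cells, stood at 262 ± 177 CPM in N and 203 ± 34.0 in BT-T and was not called. The remaining lists, which cover tuft cells, epithelium in general, enteric neurons and glia, mast cells, skeletal muscle, antimicrobial defence, glycolysis, BMP response, mismatch repair and sex-linked transcripts, were not called (camera adjusted p 0.137 to 0.995). Of these, the glycolysis, BMP and sex-linked lists had a median below 0 and a camera direction above it. The sex-linked list joins Xist with Y-linked transcripts, which offset each other, so a missing call does not mean that the groups are alike in sex. Of 18 lymphocyte markers in the files, 2 had enough reads to be tested. Of the 23 lists called, 11 were also called with an estimated correlation (adjusted p = 0.0383 for each): absorptive, goblet, fetal-like, squamous, TGF-beta, p53, matrix, epithelial-mesenchymal, interferon, fatty acid oxidation and adipocyte. Of the 23, the WNT, gastric and proliferation lists were not called without the 3 libraries with the fewest detected genes (adjusted p 0.0934 to 0.461), nor the WNT and enteroendocrine lists with the trend on transcript length removed (adjusted p 0.0692 to 0.132).

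**Figure D2:**
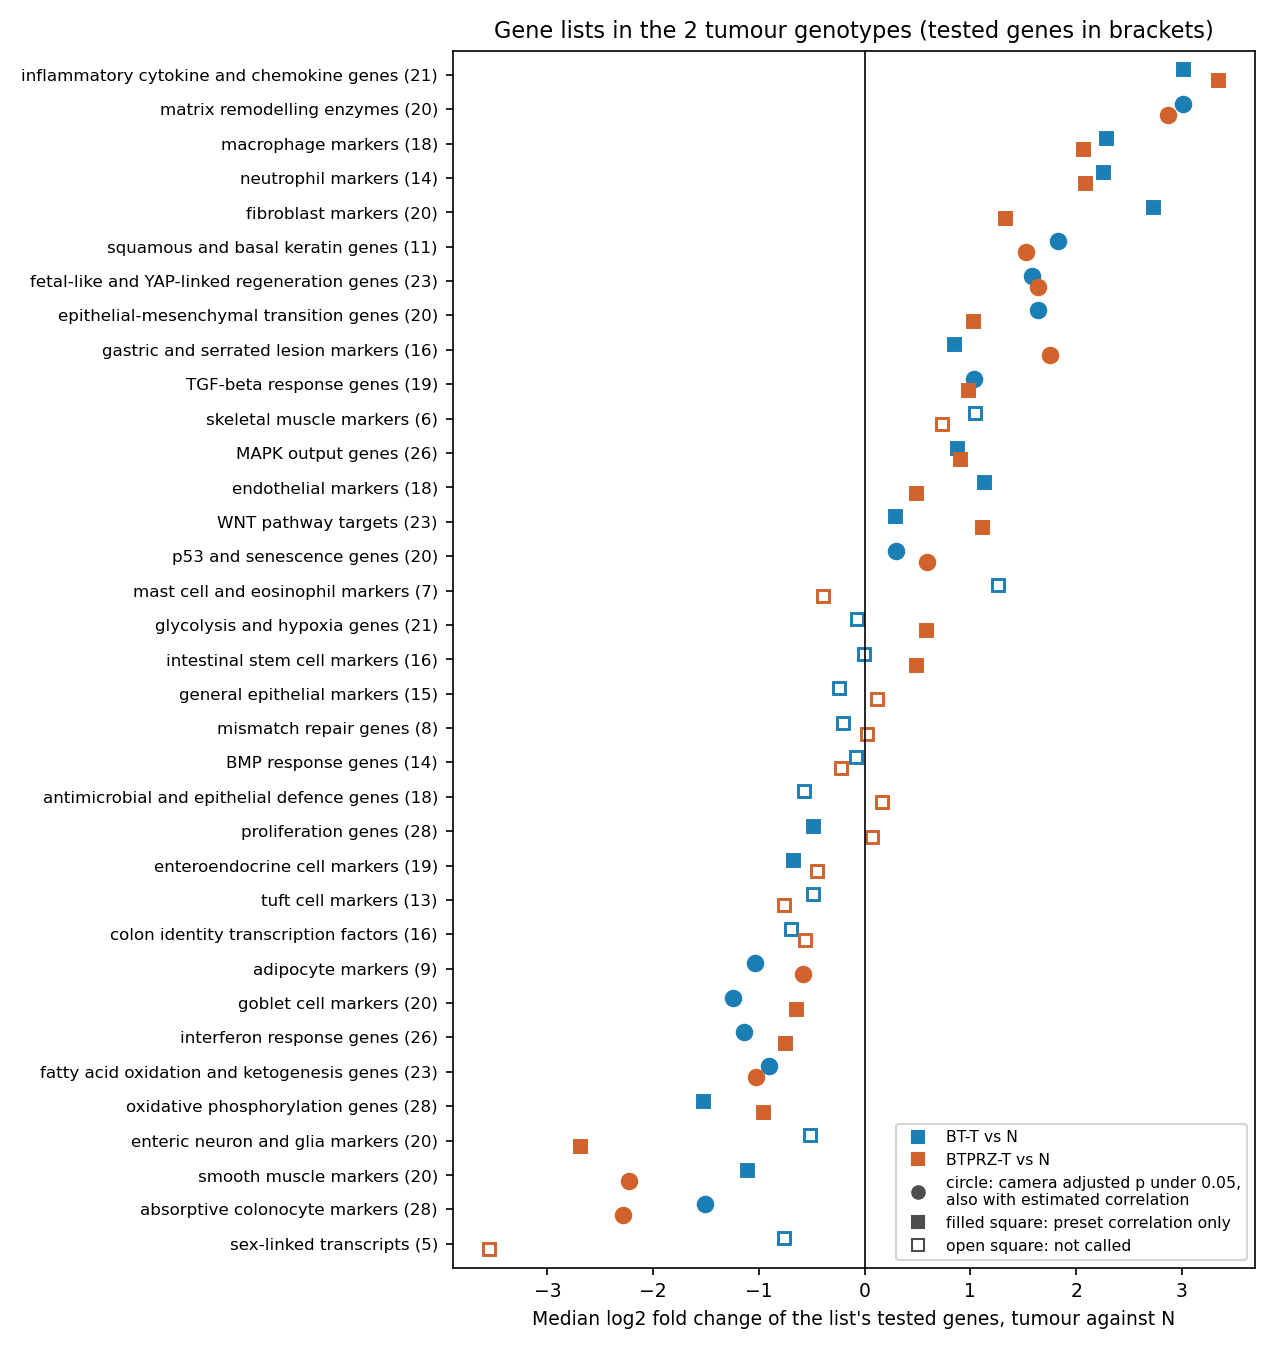
Median log2 fold change of each gene list against N in both tumour genotypes, n = 4 libraries per group. Circles mark lists called by camera (adjusted p under 0.05) also with an estimated correlation, filled squares those called at the preset correlation alone and open squares those not called.

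The second comparison asked which transcripts separate tumours with the added losses of Rnf43, Znrf3 and p16 Ink4a from normal colon. Transcripts of absorptive cells and smooth muscle were scarcer in BTPRZ-T than in N, and gastric, fetal-like and matrix-degrading transcripts were more abundant. Car1, a carbonic anhydrase of colonocytes, fell from 1826 ± 963 to 172 ± 19.9 CPM (log2 fold change -3.41 ± 0.52, n = 4 each, edgeR adjusted p = 0.00166). Pln, phospholamban of muscle cells (chromosome 10, 53337667 to 53345987), fell from 30.7 ± 13.1 to 0.0538 ± 0.0399 CPM (-9.03 ± 0.74, adjusted p = 0.000105). The stomach gene Gkn1 (chromosome 6, 87345650 to 87350942) rose from 0.0655 ± 0.0554 to 23.8 ± 28.4 CPM (8.42 ± 1.70, adjusted p = 0.00768). In all, edgeR called 1760 of 14860 genes, 841 higher and 919 lower in BTPRZ-T, of which 774 and 825 differed at least 2-fold. The count was 1076 without N replicate 1, 4855 without N replicate 2 (2496 higher) and 1134 without N replicate 3. With N and BTPRZ-T alone in the fit it was 647, DESeq2 called 3048, a test against a fold of 1.5 called 1015, 5311 were called without the 3 libraries with the fewest detected genes and 8211 by voom with sample quality weights.

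Gastric, fetal-like and squamous lists were higher in BTPRZ-T and the absorptive list lower. Of 16 gastric and serrated lesion markers, 8 rose; adjusted over the list alone, 8 rose and 1 fell (camera adjusted p = 1.91e-07). Aqp5 rose from 0.189 ± 0.0756 to 55.8 ± 40.2 CPM and Msln by 5.55 ± 0.63 on the log2 scale. Anxa10 had 8 reads in BTPRZ-T and Muc5ac 19, too few for a test. Those of Anxa10 all lay in BTPRZ-T replicate 2, and those of Muc5ac in BTPRZ-T replicates 2 and 3. Of 23 fetal-like genes, 9 rose (12 adjusted over the list alone; camera adjusted p = 1.93e-13), among them Clu (5.38 ± 0.66) and Ly6a (3.24 ± 0.53). Of 11 squamous and basal keratin genes, 3 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00103), with Krt4 at 6.55 ± 0.70. Other genes among the largest rises were the autophagy gene Atg9b (7.16 ± 0.63), Chit1 (8.17 ± 1.18), Serpinb11 (7.60 ± 1.00) and the transcription factor Pax9 (7.26 ± 1.11). Ppef1 had 456 reads in BTPRZ-T and 2 in N (95% counting interval of the ratio 51.8 to 1558). The transcription factor Onecut3 had 735 and 3 reads (68.9 to 982; adjusted p = 0.0501 without N replicate 3). Khdc1a (7.20 ± 1.71) and Mmp7, matrilysin (7.12 ± 1.71), lost their calls without N replicate 1 or 3. The adjusted p was then 0.0548 and 0.0514 for Khdc1a, and 0.0582 and 0.0565 for Mmp7. Of 28 absorptive markers, 15 fell (18 adjusted over the list alone; camera adjusted p = 3.28e-12), such as Cyp2c55 (-5.69 ± 0.62) and the chloride exchanger Slc26a3 (-4.02 ± 0.56). Krt20 was not called (adjusted p = 0.738). Ugt2b5 and Ugt2b36 had 1 and 2 reads in BTPRZ-T and 1270 and 327 in N (intervals of the ratio of N to BTPRZ-T 276 to 60859 and 54.4 to 1644), and Cyp2c69 fell by 7.49 ± 1.01 and Btnl1 by 6.81 ± 1.20. Of 20 goblet markers, 4 fell and 1 rose (5 and 1 adjusted over the list alone). Atoh1 fell by 2.29 ± 0.31 and Clca3 by 3.54 ± 0.66. The goblet list was called lower (camera adjusted p = 0.0315; adjusted p = 0.290 with an estimated correlation) but not without N replicate 2 (adjusted p = 0.143), BTPRZ-T replicate 2 (adjusted p = 0.0752) or BTPRZ-T replicate 4 (adjusted p = 0.0663). Muc2 had an adjusted p of 0.0472 and lost the call without N replicates 1, 3 or 4, any BT-T library, or BTPRZ-T replicates 1, 2 or 4 (adjusted p 0.0662 to 0.159). Of 16 colon identity factors, 5 fell and 1 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.0788, and 0.00701 without N replicate 2), with Cdx1 at -1.74 ± 0.23 and Hoxd12 at 5.30 ± 0.80. Cdx2 stood at 237 ± 74.4 CPM in N and 157 ± 41.7 in BTPRZ-T (adjusted p = 0.223, and 0.0422 without N replicate 2). Of 19 enteroendocrine markers, 2 rose and 2 fell (2 and 4 adjusted over the list alone), with Cpe at 1.57 ± 0.33 and Gcg at -4.36 ± 0.47.

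The p53 list was higher in BTPRZ-T, and WNT, stem cell, MAPK, TGF-beta and glycolysis lists at the preset correlation alone. Of 23 WNT pathway targets, 10 rose and 2 fell (11 and 3 adjusted over the list alone). The list holds Rnf43 and Znrf3, both edited in BTPRZ-T, and Rnf43 is among those that rose. Sp5 rose by 5.11 ± 0.89 and Cd44 by 1.51 ± 0.28, while the feedback inhibitor Nkd1 fell by 2.08 ± 0.45 on the log2 scale. Axin2 stood at 64.0 ± 29.8 and 59.5 ± 15.9 CPM and was not called. The WNT list stood higher (camera adjusted p = 0.000489; adjusted p = 0.290 with an estimated correlation), with an adjusted p of 0.0647 without N replicate 2. Its mean log2 CPM was 3.06 in N replicate 2 and 4.13 to 4.38 in the other N libraries. Of 16 stem cell markers, 4 rose and 2 fell (5 and 2 adjusted over the list alone), with Clu highest in BTPRZ-T at 3007 ± 450.0 CPM and Aqp4 at -4.48 ± 0.50. The stem list was called higher (camera adjusted p = 0.0291; adjusted p = 0.397 with an estimated correlation), though not without N replicate 2 (adjusted p = 0.343) or BTPRZ-T replicate 4 (adjusted p = 0.0663). Lgr5 had an adjusted p of 0.0377 (log2 fold change 1.11 ± 0.31) and lost the call without N replicates 1 or 3, any BT-T library or BTPRZ-T replicate 4 (adjusted p 0.0511 to 0.101). Of 26 MAPK output genes, 10 rose; adjusted over the list alone, 14 rose and 1 fell (camera adjusted p = 5.51e-08; adjusted p = 0.108 with an estimated correlation). Ier3 rose by 2.92 ± 0.41 and Plaur by 1.65 ± 0.25. Dusp6 had an adjusted p of 0.0498, and it was 0.0668 to 0.134 without N replicates 1 or 3, any BT-T library, or BTPRZ-T replicates 2, 3 or 4. Of 19 TGF-beta response genes, 5 rose (6 adjusted over the list alone; camera adjusted p = 1.80e-05; adjusted p = 0.108 with an estimated correlation), such as Tgfb1 (2.53 ± 0.39) and Tgif1 (1.33 ± 0.18). Smad7 was not called with all libraries and had an adjusted p of 0.00285 (lower) without N replicate 2. Of 20 p53 and senescence genes, 7 rose (8 adjusted over the list alone; camera adjusted p = 1.91e-07), with Igfbp3 at 1.82 ± 0.30. The p53 list holds Cdkn2a, which encodes the deleted p16 Ink4a and is among those that rose. Of 21 glycolysis and hypoxia genes, 7 rose, the same number adjusted over the list alone. The oxygen sensor Egln3 rose by 2.52 ± 0.31 and the carbonic anhydrase Car9 by 1.51 ± 0.30 (camera adjusted p = 0.000594; adjusted p = 0.0872 with an estimated correlation).

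Smooth muscle and adipocyte lists were lower in BTPRZ-T and the matrix list higher; neuron, fibroblast, endothelial and immune lists were called at the preset correlation alone. Of 20 smooth muscle markers, 16 fell (20 adjusted over the list alone; camera adjusted p = 4.48e-18), such as Synpo2 (-4.14 ± 0.51) and Lmod1 (-2.75 ± 0.38). Of 20 enteric neuron and glia markers, 7 fell (11 adjusted over the list alone; camera adjusted p = 1.23e-07; adjusted p = 0.115 with an estimated correlation). Snap25, a protein of synaptic vesicle release, fell by 2.69 ± 0.41, and Nos1, the neuronal nitric oxide synthase, had 1 read in BTPRZ-T and 900 in N (95% counting interval of the ratio of N to BTPRZ-T 195 to 43142). Dpp10 had no read in BTPRZ-T and 683 in N, at least 270.4-fold lower. Colec10 had 1 read against 1779 (interval 387 to 85232) and Car3 2 against 690 (interval 115 to 3460.5). Of 9 adipocyte markers, 3 fell, the same number adjusted over the list alone (camera adjusted p = 0.00145). Cfd had no read in BTPRZ-T and 533 in N, at least 218-fold lower, and Plin4 fell by 3.66 ± 0.56. Of 20 matrix remodelling enzymes, 12 rose (14 adjusted over the list alone; camera adjusted p = 3.31e-14), such as Plat (3.04 ± 0.33) and Mmp13 (4.80 ± 0.74). Of 20 fibroblast markers, 7 rose; adjusted over the list alone, 11 rose and 1 fell (camera adjusted p = 0.000156; adjusted p = 0.397 with an estimated correlation). Col5a2 rose by 1.79 ± 0.36 and Col1a1 by 2.33 ± 0.54, which lost its call without N replicate 1 (adjusted p = 0.0549). Of 20 epithelial-mesenchymal transition genes, 4 rose (7 adjusted over the list alone; camera adjusted p = 0.00105; adjusted p = 0.326 with an estimated correlation), with Loxl2 at 1.09 ± 0.28 (adjusted p = 0.0807 without N replicate 1 and 0.0528 without BTPRZ-T replicate 4). Of 18 endothelial markers, 2 rose, the same number adjusted over the list alone, with Cdh5 at 169 ± 65.5 CPM against 29.8 ± 7.40 in N (camera adjusted p = 0.0214; adjusted p = 0.464 with an estimated correlation). The endothelial list was not called without N replicate 2 (adjusted p = 0.242) or BTPRZ-T replicate 4 (adjusted p = 0.0960). Of 18 macrophage markers, 7 rose (11 adjusted over the list alone; camera adjusted p = 3.92e-06; adjusted p = 0.278 with an estimated correlation), such as the surface receptor Trem2 (4.03 ± 0.94). Emr1 (2.01 ± 0.51) lost its call without N replicates 1 or 3 or BTPRZ-T replicate 4 (adjusted p 0.0580 to 0.0722). Of 14 neutrophil markers, 5 rose (6 adjusted over the list alone; camera adjusted p = 6.72e-06; adjusted p = 0.0811 with an estimated correlation), with Csf3r at 3.44 ± 0.59. Of 21 cytokine and chemokine genes, 10 rose (14 adjusted over the list alone; camera adjusted p = 4.49e-10; adjusted p = 0.108 with an estimated correlation), among them Ccl3 (6.22 ± 0.97) and Il1a (5.78 ± 0.89).

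The fatty acid oxidation list was lower in BTPRZ-T, and oxidative phosphorylation and interferon lists at the preset correlation alone. Of 23 genes of fatty acid oxidation and ketogenesis, 14 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 1.47e-09). Bdh1 fell by 1.64 ± 0.20 on the log2 scale. Of 28 oxidative phosphorylation genes, 3 fell (5 adjusted over the list alone), with Ndufs1 at -1.01 ± 0.17 (camera adjusted p = 0.000256; adjusted p = 0.511 with an estimated correlation). Without N replicate 2, where this list is highest, it was not called (adjusted p = 0.212). Of 26 interferon response genes, 7 fell and 1 rose (13 and 1 adjusted over the list alone), with Isg15 at -2.71 ± 0.45 and Ifit2 at -1.56 ± 0.32. The interferon list stood lower (camera adjusted p = 0.000628; adjusted p = 0.293 with an estimated correlation; 0.0968 without the 3 libraries with the fewest detected genes). Of 18 antimicrobial and epithelial defence genes, 4 rose and 1 fell, the same numbers adjusted over the list alone, with the Paneth cell lysozyme Lyz1 at 4.27 ± 0.82. Mki67 stood at 262 ± 177 and 174 ± 58.3 CPM and was not called. The antimicrobial, enteroendocrine, tuft cell, general epithelial, proliferation, mast cell, skeletal muscle, BMP, mismatch repair and sex-linked lists were not called (camera adjusted p 0.115 to 0.974). Of these, the enteroendocrine list was called without BTPRZ-T replicate 3 (adjusted p = 0.0449), the general epithelial list without BTPRZ-T replicate 4 (adjusted p = 0.0488) and the sex-linked list without BTPRZ-T replicate 2 (adjusted p = 0.0498). As in BT-T, the missing call of the sex-linked list with all libraries does not mean that the groups are alike in sex. Of the 24 lists called, 9 were also called with an estimated correlation (adjusted p 0.0225 to 0.0410): gastric, fetal-like, absorptive, squamous, adipocyte, matrix, smooth muscle, fatty acid oxidation and p53. Of the 24, the WNT, stem cell, goblet, epithelial-mesenchymal, fibroblast, endothelial and interferon lists were not called without the 3 libraries with the fewest detected genes (adjusted p 0.0968 to 0.485).

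Both tumour genotypes changed many genes in the same direction. Of the genes called against N, 516 were higher in both genotypes and 243 lower in both, 759 in all, and none was called in opposite directions with all N libraries in both comparisons. Lists of these sizes drawn independently would share 47.7 and 26.7 genes. Both comparisons use the same 4 N libraries, which alone makes their fold changes alike. In 20 simulations with tumour libraries no different from N, the covariance of the log2 fold changes was 0.175 on average and r was 0.50, against 1.30 and 0.71 here, across 14860 genes that are not independent. Fold changes had the same sign in 71.9% of genes, against 66.8% in the simulations. With the N libraries divided 2 and 2 between both comparisons, in each of 6 ways, 292 to 387 genes were called in the same direction, where lists drawn independently would share 15.0 to 90.8. The covariance was 0.789 to 1.29 and r 0.317 to 0.657. In the 3 ways with N replicate 2 on the side of BT-T, 7, 2 and 6 genes were called in opposite directions, and in the other 3 none. The count of 759 was 439, 1473 and 496 without N replicates 1, 2 and 3, and 448 and 458 without BT-T replicates 2 and 3. It was 378 with each pair of groups fitted alone and 1444 by DESeq2.

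**Figure D3:**
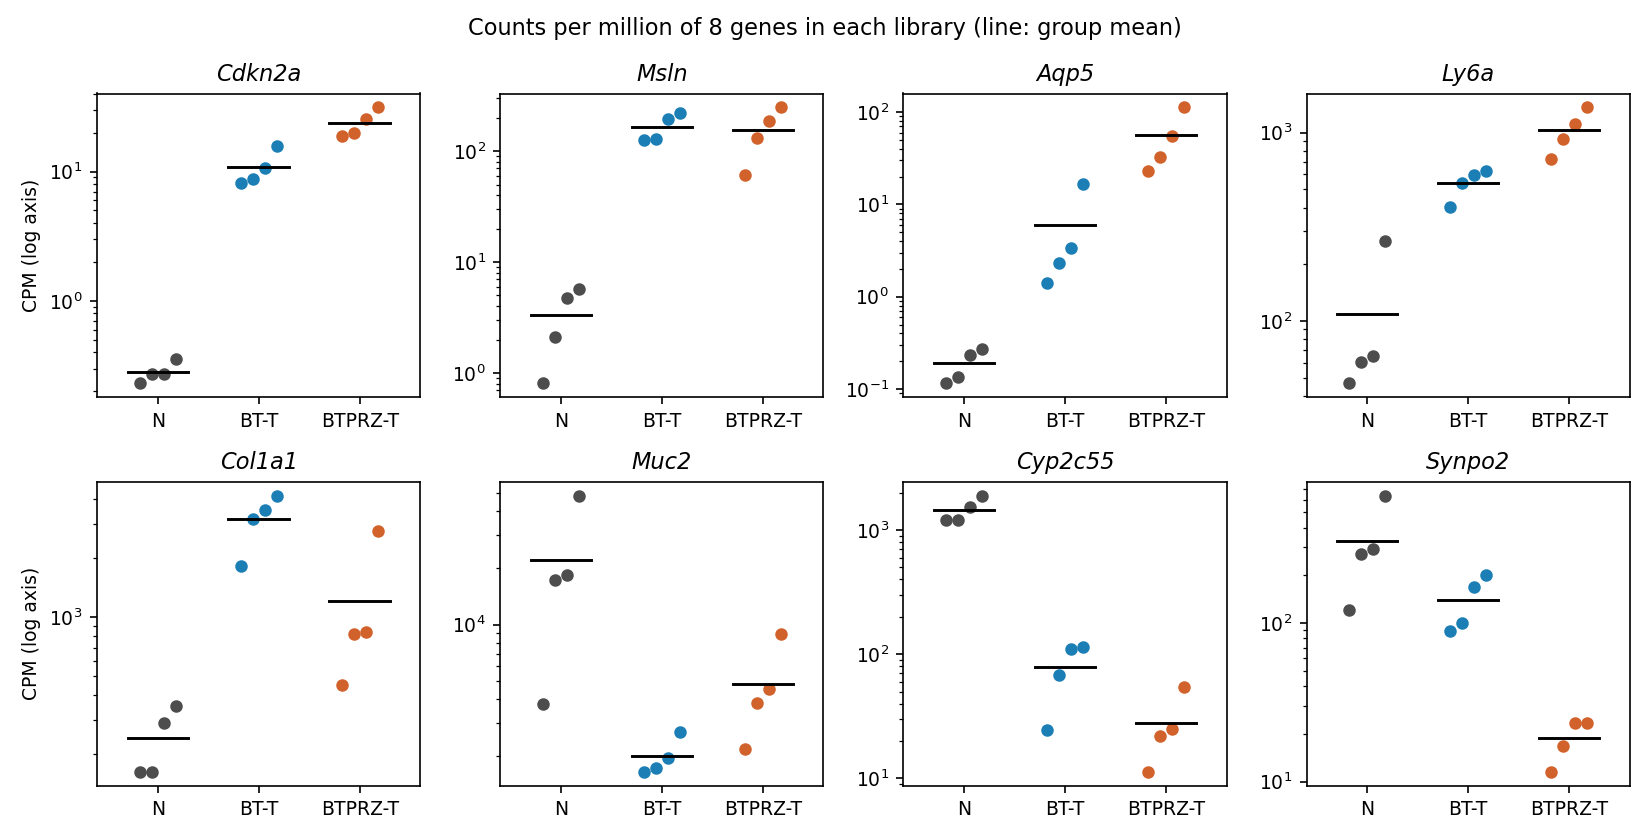
Levels of 8 genes in each library in CPM on a log axis, n = 4 libraries per group, with group means as lines. Cdkn2a, Msln, Aqp5 and Ly6a are higher in both tumour groups than in N, Cyp2c55 is lower in both, and Synpo2 is lowest in BTPRZ-T.

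The third comparison asked how tumours with the added losses differ from tumours without them, and it was also the test of the difference between both tumour effects. Some genes of muscle and nerve were scarcer in BTPRZ-T than in BT-T, and some hypoxia-induced and secretory genes were more abundant. Car9, a hypoxia-induced carbonic anhydrase (chromosome 4, 43506966 to 43513729), rose from 36.5 ± 10.4 to 138 ± 47.3 CPM (log2 fold change 1.92 ± 0.31, n = 4 each, edgeR adjusted p = 0.0285). Synpo2, an actin-binding protein of smooth muscle, fell from 139.7 ± 53.7 to 18.7 ± 5.74 CPM (-2.90 ± 0.48, adjusted p = 0.0285). Amph, a protein of synaptic vesicle recycling, fell from 17.8 ± 8.61 to 0.0562 ± 0.0663 CPM (-8.23 ± 1.10, adjusted p = 0.0159). In all, edgeR called 112 genes, 23 higher and 89 lower in BTPRZ-T, of which 21 and 88 differed at least 2-fold. With a term for the replicate number, edgeR called 1 gene, with 2297 at an unadjusted p under 0.05. The labels do not say that these numbers pair the samples. Without BT-T replicate 2, BT-T replicate 4 or BTPRZ-T replicate 3, edgeR called 0 genes, with 1669, 1662 and 2509 at an unadjusted p under 0.05; on all libraries DESeq2 called 1217 and limma with voom 266. The count was 24, 2714 and 61 without N replicates 1, 2 and 3, 9 without BT-T replicate 1, and 21, 14 and 400 without BTPRZ-T replicates 1, 2 and 4; it was 1568 with both tumour groups alone in the fit, 8 against a fold of 1.5, 214 with the trend on transcript length removed, 3723 without the 3 libraries with the fewest detected genes and 7734 by voom with sample quality weights. The division by direction was not stable: 1476 were higher and 1238 lower without N replicate 2, 751 and 817 with both tumour groups alone, 1477 and 2246 without the 3 libraries, 3640 and 4094 with quality weights and 331 and 886 by DESeq2.

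The genes with the largest changes between the tumour genotypes belong to several tissues. Higher in BTPRZ-T were the tryptophan-degrading enzyme Ido1 (5.02 ± 0.99), the hormone gene Cck (3.82 ± 0.62), Soat2 (2.80 ± 0.58), Cd177 (2.72 ± 0.34), the potassium channel Kcnh3 (2.44 ± 0.46), the long non-coding RNA Pvt1 (2.09 ± 0.40), Car8 (2.08 ± 0.35), Ccdc141 (1.89 ± 0.39) and Spdef (1.81 ± 0.37). Lower were Nat8l (-5.59 ± 0.73), the synaptotagmin Syt4 (-5.22 ± 0.86), Cmah (-4.46 ± 0.63), Clec3b (-3.18 ± 0.61), the transcription factors Foxp2 (-2.90 ± 0.48) and Bnc2 (-2.73 ± 0.52), and Mfap3l (-2.78 ± 0.57). Nos1 had 1 read in BTPRZ-T and 583 in BT-T (95% counting interval of the ratio of BT-T to BTPRZ-T 86.8 to 19211). The adjusted p of these genes and of Car9, Synpo2 and Amph lay between 0.0159 and 0.0489. All of the 23 called genes named for this comparison lost the call without BT-T replicate 2 (adjusted p up to 0.180), BT-T replicate 4 (up to 0.194) or BTPRZ-T replicate 3 (up to 0.146). Of them, 19, 18, 17, 16, 9, 8, 4 and 1 lost it without BT-T replicate 1, BTPRZ-T replicates 1 and 2, N replicates 1, 3 and 4, BT-T replicate 3 and BTPRZ-T replicate 4 (adjusted p up to 0.140). With a term for the replicate number, 22 of the 23 lost it (edgeR adjusted p 0.0640 to 0.114).

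Camera called 15 lists between the tumour genotypes at the preset correlation and none with an estimated one, where 5 had an unadjusted p under 0.05. Of 20 smooth muscle markers, 2 fell (12 adjusted over the list alone; camera adjusted p = 1.22e-10; adjusted p = 0.322 with an estimated correlation), Synpo2 and Lmod1 (-2.02 ± 0.37). Of 20 enteric neuron and glia markers, 1 fell, Nos1 (9 adjusted over the list alone; camera adjusted p = 2.52e-08; adjusted p = 0.322 with an estimated correlation). The fibroblast list (11 of 20 lower adjusted over the list alone; camera adjusted p = 9.12e-10; adjusted p = 0.323 with an estimated correlation) and the epithelial-mesenchymal list (3 of 20 lower adjusted over the list alone; camera adjusted p = 3.76e-06; adjusted p = 0.322 with an estimated correlation) also stood lower. Col5a2 stood at 722 ± 144 CPM in BT-T and 265 ± 135 in BTPRZ-T (adjusted p = 0.0828, and 0.0155 and 0.0308 without N replicate 2 and BTPRZ-T replicate 4). The endothelial list (2 of 18 lower adjusted over the list alone; camera adjusted p = 0.000879; adjusted p = 0.331 with an estimated correlation) and the mast cell list (camera adjusted p = 0.0299; adjusted p = 0.323 with an estimated correlation) were lower as well. The glycolysis and hypoxia list stood higher, with 2 of 21 genes called (7 adjusted over the list alone), Car9 and Egln3 (1.59 ± 0.30; camera adjusted p = 3.76e-05; adjusted p = 0.310 with an estimated correlation). So did the goblet list, with 1 of 20 called, Spdef (adjusted over the list alone, 3 rose and 1 fell; camera adjusted p = 0.0350; adjusted p = 0.331 with an estimated correlation), and the gastric list (5 of 16 higher adjusted over the list alone; camera adjusted p = 0.000222; adjusted p = 0.322 with an estimated correlation). Aqp5 stood at 5.96 ± 7.25 CPM in BT-T and 55.8 ± 40.2 in BTPRZ-T (adjusted p = 0.0734, and 0.0158 and 0.0107 without N replicate 2 and BT-T replicate 3). The proliferation, interferon, stem cell, antimicrobial, general epithelial and oxidative phosphorylation lists were called higher too (camera adjusted p 2.54e-05 to 0.0158; adjusted p 0.331 to 0.657 with an estimated correlation). No member of these 6 lists was called; adjusted over the list alone, 3 interferon, 4 antimicrobial and 1 general epithelial genes rose and none of the other 3 lists. Mki67 stood at 203 ± 34.0 CPM in BT-T and 174 ± 58.3 in BTPRZ-T and was not called (adjusted p = 0.807). Beside the oxidative phosphorylation and proliferation lists stand the shares of ribosomal protein reads, 2.26 ± 0.361% in BT-T and 5.73 ± 2.37% in BTPRZ-T. With the trend on transcript length removed, the goblet, general epithelial, antimicrobial and oxidative phosphorylation lists were not called (adjusted p 0.103 to 0.524) and 6 others were. Without the 3 libraries with the fewest detected genes, the goblet, mast cell, antimicrobial and oxidative phosphorylation lists were not called (adjusted p 0.0643 to 0.105) and 2 others were. The remaining lists were not called (camera adjusted p 0.0643 to 0.816), and the tuft, squamous, neutrophil and adipocyte lists had a median and a camera direction of opposite sign. The goblet list was not called without N replicate 2, BT-T replicate 2 or BTPRZ-T replicate 3 (adjusted p 0.0553 to 0.0763), the general epithelial list without BTPRZ-T replicate 3 (adjusted p = 0.0847) and the oxidative phosphorylation list without BTPRZ-T replicate 1 (adjusted p = 0.0558). The mast cell list was not called without N replicates 2 or 4 or BTPRZ-T replicates 1, 3 or 4 (adjusted p 0.0526 to 0.106). The macrophage list was called lower in BTPRZ-T without BTPRZ-T replicate 4 (adjusted p = 0.00171).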

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

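Tests of explanations in this part were chosen after the result was seen, apart from the tests of transcript length as the whole cause and of a label swap in N replicate 2, which were written first. In each group of 4 libraries, 1 library was singled out when its gap to the nearest of the others took a larger part of the group's range than Dixon's 95% critical value allows. Over 119 genes and 8 library measures this was met in 29 of 379 groups, where chance gives about 18.95. Genes with reads in 1 library of a group alone meet this by construction, so the excess over chance rests in part on them.

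Single N libraries stood apart for several genes. N replicate 2 was lower than the other 3 for Znrf3 (0.855 of the range), Axin2 (0.831), Smad7 (0.910) and Amph (0.902), and higher for Dynap (0.842). N replicate 1 was lower for Col5a2 (0.917) and Cdh11 (0.944), N replicate 4 higher for Pmepa1 (0.916) and N replicate 3 higher for Plin4 (0.903). In N replicate 2 the number of genes with a read (0.876), the slope on transcript length (0.925) and the ribosomal protein share (0.962) also lay apart. Of the 29, 6 were genes in this library. Itgbl1 in N replicate 2, Epyc and Onecut3 in N replicate 1, Ugt2b5, Colec10 and Nos1 in BTPRZ-T replicate 2, and Ugt2b36 and Car3 in BTPRZ-T replicate 3 had reads in that 1 library of their group alone, so the gap is the whole range (1).

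Single tumour libraries stood apart too. BT-T replicate 1 was low for Acan (0.841 of the range) and Cdh5 (0.854), BT-T replicate 4 low for Il1a (0.887) and BT-T replicate 3 high for Onecut3 (0.883). BTPRZ-T replicate 1 was high for Lyz1 (0.917). BTPRZ-T replicate 4 was low for Wif1 (0.864) and Clca3 (0.840), BTPRZ-T replicate 3 low for Bnc2 (0.920) and BTPRZ-T replicate 2 low for Tgif1 (0.837).

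The change from N differed between the tumour genotypes for 112 genes by edgeR, a test of the difference itself. Among genes named against N, the log2 change in BTPRZ-T minus that in BT-T was -8.18 for Dpp10, -5.41 for Colec10, -8.46 for Nos1, -5.12 for Pln, -2.90 for Synpo2, -2.73 for Plin4 and -2.02 for Lmod1. It was 2.72 for Cd177, 1.92 for Car9, 1.81 for Spdef and 1.59 for Egln3. Dpp10, Colec10 and Nos1 had 0 or 1 read in BTPRZ-T, so their fitted values depend on the prior count and are no bound. The count was 0 without BT-T replicate 2, BT-T replicate 4 or BTPRZ-T replicate 3 (edgeR; 1669, 1662 and 2509 genes at an unadjusted p under 0.05; DESeq2 called 1217 and limma with voom 266 on all libraries). It was 24, 2714 and 61 without N replicates 1, 2 and 3, 9 without BT-T replicate 1, and 21, 14 and 400 without BTPRZ-T replicates 1, 2 and 4. With a term for the replicate number it was 1.

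N replicate 2 held more ribosomal protein reads than the other N libraries, and its levels fell with transcript length (slope -1.01 over 14130 other genes), so a bias against long transcripts may be part of the cause. As the whole cause it missed its prediction. Ribosomal protein genes deviated by a median of 2.95 log2 units, and 1000 sets of genes matched on length and level gave 0.952 to 1.78 (central 95%). Length was that of the longest annotated transcript, which need not be the one expressed. The sets may thus differ from these genes in true length, so the test cannot decide. A swap of labels with a BTPRZ-T library is argued against. Between N (0) and BTPRZ-T (1) N replicate 2 lay at 0.734 and no BTPRZ-T library lay below 0.794, which leaves no partner. A BTPRZ-T library labelled N without a swap was not tested, and 0.734 is near that lowest position. Cdkn2a stood at 0.271 CPM in N replicate 2 and at 18.8 to 31.4 in BTPRZ-T. Mean log2 CPM was 7.49 against 5.30 to 6.13 for the absorptive list and 8.24 against 4.44 to 6.61 for smooth muscle. For the p53 list it was 4.60 against 5.79 to 5.90. These genes argue against such a library, though Muc2 and the antimicrobial list lay within the BTPRZ-T range. Between N (0) and BT-T (1) N replicate 2 lay at 0.166 over 1498 genes, which argues against a BT-T library under this label. The position was 0.0987 for genes higher in BT-T and 0.398 for genes lower, so the latter argue less clearly. RNA of other cells stays open. Of 11 lists of other cell types, the macrophage list had the highest median deviation, 1.42. The neuron and endothelial lists lay at -1.22 and -0.919 and the others at -0.0767 to 0.183. Over 17 genes the macrophage median was 1.66 against -0.22 to 1.41 in matched sets, with no allowance for taking the highest list. The most abundant were Cd14 (269 CPM against 81.1 to 153 in the other N libraries), Lyz2 (209 against 26.9 to 76.1) and Ctss (177 against 92.5 to 198), Csf1r was lower (3.72 against 9.44 to 31.8), 16 of the 18 markers stand at 1 CPM or more in the other N libraries and none is in another list, and no biological explanation was tested.

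Xist and Y-linked transcripts stood together in BT-T replicates 2, 3 and 4 and BTPRZ-T replicate 2, and a candidate explanation is cells of both sexes in 1 tumour, such as engrafted cells and host stroma of different sex. Taking N replicates 1 to 3 in turn as the reference for Y-linked transcripts, the Y share ran from 0.653 to 0.925, 0.551 to 0.768, 0.583 to 0.813 and 0.219 to 0.328 in these 4 libraries. The 5 libraries with Xist and a Y share of at most 0.00160 held 505 to 1549 CPM of Xist. With each of them as the reference, the Xist share ran from 0.136 to 0.417, 0.256 to 0.784, 0.0619 to 0.190 and 0.472 to 1.45. In BT-T replicates 2 and 4 the sums of both shares lay between 0.645 and 1.34, around the 1 of a mixture, which argues there against both in the same cells, where the sum would be near 2. In BT-T replicate 3 and BTPRZ-T replicate 2 they lay between 0.691 and 1.77, and both explanations cannot be told apart there, since the sum depends on the Xist reference. RNA carried over from an N library is argued against, since the 10 named genes lower in tumours of each genotype stood at a median of at most 0.00758 of their N level there. The labels give the sex of neither host nor donor, so no biological explanation was tested.

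BT-T replicate 3 held intermediate levels of 14 genes that were high in every BTPRZ-T library and low in the other BT-T libraries, among them Khdc1a, Chit1, Pax9, Reg3b, Gkn1, Ido1 and Mmp7. Their rise over the mean of the other BT-T libraries was 0.0914 to 0.525 of the distance to the BTPRZ-T mean (median share 0.2003). Their median level was 0.223 of the BTPRZ-T mean. A BTPRZ-T library under the wrong label is argued against, since over all tested genes BT-T replicate 3 correlated with the other BT-T libraries by at least 0.970 and no BTPRZ-T library by more than 0.939. Of 90 genes called between the genotypes without it and changed at least 2-fold, 89 lay beyond the BTPRZ-T range in this library, at a median position of 0.353 between the other BT-T libraries (0) and BTPRZ-T (1). On genes called without BTPRZ-T replicates 1, 2 and 4 in turn, 14 of 21, 10 of 14 and 284 of 393 lay beyond the range of the other BTPRZ-T libraries, at 0.691, 0.776 and 0.378, so the position by itself does not decide. RNA of 1 or several BTPRZ-T libraries stays open. The highest share was 3.84 to 49.3 times the lowest with 1 library as the source, 5.74 times with equal parts of all 4 and 2.64 times with the best of 176851 mixtures. These data do not show how far the share of carried RNA varies between genes. A tumour of BT-T genotype that itself expresses these genes also stays open and was not tested.

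The 8 libraries of each comparison were divided into groups of 4 in all 35 ways and fitted again. For BT-T against N, 1 of 35 splits, the real one, gave 1274 genes or more, with 0 in the highest other split. That is the smallest share that 35 splits can give. Mixed groups also carry the group difference in their spread, which lowers their counts. The result argues against chance for the gene count without excluding it. For the lists, 2 of 35 gave 23 or more (highest other 24), and chance is not excluded. For BTPRZ-T against N, 2 of 35 gave 1760 genes or more and 6 gave 24 lists or more (highest others 4072 and 25), and chance is excluded for neither. The split with 4072 genes set N replicates 1, 3 and 4 with BTPRZ-T replicate 3 against the rest, so N replicate 2 and BTPRZ-T replicate 3 exchange sides, and it points to a structure of the samples apart from genotype. For BTPRZ-T against BT-T, 1 of 35, the real one, gave 112 genes or more (highest other 1). This argues against chance for the gene count within the same limits and does not exclude it. The count was 0 without BT-T replicate 2, BT-T replicate 4 or BTPRZ-T replicate 3. For the lists, 9 gave 15 or more (highest other 22), and chance is not excluded.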

How the results depend on the processing

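Fits with the length trend removed, with sample quality weights, without the 3 libraries with the fewest detected genes, and without libraries of a group outside the comparison were chosen after the data were seen. No named gene or list changed sign under an alternative where it was called with all libraries or under that alternative. Changes of sign between results that were not called were not counted. The test against a fold of 1.5 was compared by its gene counts alone. Over the other alternatives, single genes stayed on their side of the threshold in 4820 tests, lost the call in 302 and gained it in 166, and lists did so in 2473, 101 and 43. Of the named genes called against N, limma with voom lost 7 of 64 in BT-T and 7 of 71 in BTPRZ-T (its adjusted p up to 0.144 and 0.0887). With the 2 compared groups alone, 0 of 62 and 9 of 69 lost the call (edgeR adjusted p up to 0.161). RLE and upper quartile factors moved the median log2 change of all genes by at most 0.0762. The counts stayed within 1.5 times of the reported ones under both, with no filter or a stricter one, on the unstranded column and without robust estimation.

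For BT-T against N the count of 1274 genes became 2394 by DESeq2, 684 against a fold of 1.5, 6156 with sample quality weights and 4359 without the 3 libraries. For BTPRZ-T against N the count of 1760 became 3048, 1015, 8211 and 5311 in the same order, 647 with those 2 groups alone and 1160 with a term for the replicate number. For BTPRZ-T against BT-T the count of 112 became 1217 by DESeq2, 266 by limma with voom, 8 against a fold of 1.5, 7734 with sample quality weights, 3723 without the 3 libraries, 1568 with those 2 groups alone, 214 with the length trend removed and 1 with a term for the replicate number. The count of 759 genes changed alike in both genotypes became 1444 by DESeq2, 378 with each pair of groups alone, 1156 with the length trend removed, 3977 with sample quality weights and 2346 without the 3 libraries. A test against a fold of 1.5 asks for a larger change by construction. For the other changes the cause was not tested. On simulated counts DESeq2 made false calls in 39.5, 44.8 and 29.8% of its calls and edgeR in 3 of 32, 1 of 33 and 0 of 26. There limma with voom made 1 of 27, 1 of 26 and 0 of 26 false calls, and voom with sample quality weights 1 of 27, 1 of 26 and 0 of 25. The simulated libraries do not differ in quality, so the weights were not tested on such differences. Each comparison had 1 draw, with dispersions estimated by edgeR and few changed genes. The shares of false calls are therefore no estimate for the calls on the real libraries.

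Libraries of 1 replicate number correlated, as deviations from their group means, by -0.297 to 0.239 in the comparisons with N, where no library matched its own number best. In BTPRZ-T against BT-T the correlation was 0.0712 to 0.315, and each BTPRZ-T library matched the BT-T library of its own number best. This is a hint from the data, not the design, and 1 of the 4 correlations is under 0.1, so the numbers were not taken as pairs. With the replicate term, 22 of the 23 called genes named for this comparison lost the call (adjusted p 0.0640 to 0.114) and none of the 15 lists did.

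Without single libraries the counts ran from 624 to 2030 in BT-T against N, 1076 to 4855 in BTPRZ-T against N, 0 to 2714 in BTPRZ-T against BT-T and 439 to 1473 for changes alike in both genotypes. The highest count in each came without N replicate 2. The lowest came without BT-T replicate 2 in BT-T against N, without N replicate 1 in BTPRZ-T against N and for changes alike, and without BT-T replicate 2, BT-T replicate 4 or BTPRZ-T replicate 3 in BTPRZ-T against BT-T. There edgeR called 0 genes, with 1669, 1662 and 2509 at an unadjusted p under 0.05, and DESeq2 called 1217 and limma with voom 266 on all libraries. Counts beyond 1.5 times also came without N replicate 1 (757), BT-T replicate 3 (688) and BT-T replicate 4 (722) in BT-T against N, and without N replicate 3 in BTPRZ-T against N (1134). In BTPRZ-T against BT-T they came without N replicates 1 and 3 (24 and 61), BT-T replicate 1 (9) and BTPRZ-T replicates 1, 2 and 4 (21, 14 and 400). For changes alike they came without N replicate 3 (496) and BT-T replicates 2 and 3 (448 and 458). Fewer libraries in the fit lower the power by construction, and the cause of the rise without N replicate 2 was not tested.

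With the correlation between genes estimated, the lists called became 11 of 23, 9 of 24 and 0 of 15 (camera; 16, 15 and 5 lists at an unadjusted p under 0.05). No other alternative moved a count of lists beyond 1.5 times. An estimated correlation widens the test by construction where members of a list move together.

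Depth limits genes with few reads. Of 24054 genes, 14860 had enough reads to be tested at 15.7M to 26.1M gene reads per library. Muc5ac and Anxa10 did not, and these data do not show whether more depth would change that. On simulated counts of this size edgeR found 28, 29 and 26 of 66 genes with a 4-fold change and 1, 3 and 0 of 67 with a 2-fold change, so smaller changes between the groups are mostly out of reach.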

Other observations

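All tests in this part were chosen after the data were seen. Genes sharing a symbol stem were grouped into 378 families and tested by camera, which called 46, 19 and 41 families in BT-T against N, BTPRZ-T against N and BTPRZ-T against BT-T at the preset correlation. With an estimated correlation it called 0 in each, with 27, 19 and 17 at an unadjusted p under 0.05; no other tool was run on families. The values below are therefore given without a claim for any family as a whole, and the families were not refitted without single libraries.

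Of 8 HoxD genes tested, 4 rose in BT-T and 4 in BTPRZ-T against N (median log2 change of the 8 genes 3.22 and 2.51). Hoxd12 stood at 0 to 0.406 CPM in the N libraries, 7.18 to 13.05 in BT-T and 2.59 to 11.2 in BTPRZ-T, and Hoxd11 at 0.230 to 3.45, 28.2 to 40.2 and 9.70 to 38.9. Hoxd10 rose in both (log2 change 4.17 ± 0.70 and 3.05 ± 0.68), Hoxd13 was called in BT-T (3.75 ± 0.97) and Hoxd8 in BTPRZ-T (2.25 ± 0.48). Each of the 8 tumour libraries stood above each N library for Hoxd10, Hoxd11, Hoxd12 and Hoxd13. HoxB genes rose in part, Hoxb3 in both genotypes (1.93 ± 0.38 and 2.46 ± 0.38) and Hoxb6, Hoxb7 and Hoxb8 in BTPRZ-T alone, where the difference between genotypes was not called. Of 12 HoxA genes, Hoxa7 fell in both (-1.52 ± 0.25 and -1.66 ± 0.25).

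Some carboxylesterase, glucuronosyltransferase and glutathione transferase genes were called lower in tumours. Of 11 Ces genes, 5 fell in BT-T and 7 in BTPRZ-T (median -1.71 and -3.10), of 9 Ugt genes 4 and 5 (-2.14 and -2.53) and of 7 Gstm genes 2 and 6 (-0.93 and -1.58). Ces1c and Ces2f went the other way in BT-T (3.57 ± 1.16 and 2.73 ± 1.20) and were not called. Of 8 genes of colony-stimulating factors and their receptors, 6 rose in BT-T and 4 in BTPRZ-T (median 3.78 and 2.59).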
